A study of Mus musculus with 4 samples.

How the data were processed

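RNA was sequenced from lung tumours of wild-type and Nrf2 knockout Balb/c mice, with 2 libraries per genotype. The mice had received vinyl carbamate, a chemical carcinogen that induces lung adenomas and carcinomas, at 16 mg/kg in 2 or 4 doses. Tumours were collected 40 to 44 weeks later, and 3 to 4 of them made up a sample. The labels do not say which sample had which number of doses, weeks or tumours. Groups were taken from the sample titles and the genotype labels.

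The deposited values are FPKM per gene, as the values themselves show: for all but 1 of the genes above 0, they fit a whole number of reads times a constant of the library, divided by a whole-number length of the gene. Alignment to mm10 and the tools TopHat2 and DESeq2 are named, with no role or version, per the submitters' processing notes. The read counter, the annotation, the gene lengths, any filters and the use of strand are not given in the sources used here. Reads shared between near-identical genes may therefore have been split, dropped or counted for several of them, and reads from overlapping genes on opposite strands cannot be told apart.

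The table lists 35275 gene identifiers, of which 34490 matched a symbol in the GENCODE annotation of GRCm38, the same assembly as mm10. Coordinates are from that annotation and count from 1. Of 21601 genes above 0, whole reads were recovered for 21600 by finding a length at which all 4 values became whole within 0.0002 reads, plus 2e-08 per read and the rounding of the file. When the values of 500 genes that passed the filter were disturbed at random by up to 1%, 0 of them fitted any length. That length was an annotated transcript or exon union length for 5488 genes, and for the others the smallest length that fitted, so that their reads could be undercounted. These steps also imply library totals of 21.66 and 21.22 M reads (1 M is 1e6) for wild type 1 and 2, and 17.98 and 16.89 M for knockout 1 and 2. A tested gene had a median of 507 reads per library, so counting error is small for most genes and large for those with few reads. Reads carry no molecular identifiers, and an interval from them covers counting error only.

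Knockout and wild-type libraries were compared with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with an intensity trend in the variance prior and Benjamini-Hochberg adjustment over 13147 genes. Genes were kept with an FPKM of at least 1 in 2 or more libraries. The plan set this limit for units scaled to library totals, and 10 for other normalized values. FPKM was assigned to the former after the unit was known, and the lower limits were likewise used in the naming rule (1, not 10) and in the stricter filter (5). An added setting uses an FPKM of at least 10. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. A gene was called at an adjusted p under 0.05. The model has 2 residual degrees of freedom and a prior worth 4.12. With 2 libraries against 2, an exact two-sided permutation test could not go below 0.333, so every p-value comes from limma's model. The series design refers to separate mice, and the p-values of single genes measure the spread between these 4 samples.

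Alternatives chosen beforehand were quantile normalization, limma without the trend, no filter on low values, a stricter filter (an FPKM of at least 5), pseudocounts of 0.1 and 10, the replicate number as a block, leaving out each library, an adjusted p under 0.1 and an absolute log2 fold change of at least 1. Added after the data were seen were limma-voom on the recovered reads, the filter at an FPKM of 10 and a filter on recovered reads (at least 10 in 2 or more libraries). The design was written before the data were examined. It named a count model as first choice for a table of counts, and its branch for normalized values was used.

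Gene lists, 44 in all, were written from textbook knowledge before the data were examined, and 38 had at least 5 tested members. They were tested with camera in limma at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. The preset value takes members as nearly independent, so those p-values also reflect the number of members. Estimated correlations ran from -0.133 for classically activated macrophage genes to 0.864 for fibroblast and matrix genes. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so that few lists could pass. For neutrophil markers the estimated correlation was -0.075, yet camera's unadjusted p went from 3.23e-09 to 0.0247. In fry, the p-value tests whether a list's genes move on balance in 1 direction, without comparing them with other genes. Members were also counted as adjusted over the list alone.

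Named genes followed a rule fixed at the same time. It takes Nfe2l2, and up to 12 called genes in each direction by fold change, with both knockout libraries on 1 side of both wild-type libraries and a mean of at least 1 (read here as FPKM). It adds up to 4 members of each list with the smallest p-values, and every called NRF2 target. Predicted genes are passed over for the 12. Genes named outside the rule are marked as chosen after their values were seen.

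The fit was tested on simulated counts for the 13147 genes with 200 changed, over 5 runs at a dispersion of 0.00702. In this simulated comparison of knockout and wild type it called 92.6% of the genes changed 2-fold and 99.4% of those changed 4-fold. All simulated genes shared this dispersion, and the changed genes had a mean of at least 20 reads. The shares therefore do not hold for genes that vary more or have fewer reads. False calls were 8.7% of all calls, above the nominal rate. A planted list of 20 genes was called in 5 of 5 runs, and 0 of 100 lists of unchanged genes were. Simulated genes varied independently of each other, so these counts do not cover lists whose members vary together. Other steps used Python 3.11.15 with scipy 1.17.1.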

Results

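Lung tumours of wild-type mice and of mice lacking Nrf2 were profiled by RNA sequencing, with 2 samples per genotype, each pooled from several tumours. Nrf2, encoded by Nfe2l2, is a transcription factor that activates antioxidant and detoxification genes. The comparison asks how established tumours differ in expression when the gene is missing from the whole animal. Library totals implied by the values were 21.66 and 21.22 M reads (1 M is 1e6) for wild type 1 and 2, against 17.98 and 16.89 M for knockout 1 and 2. Sftpc, which encodes surfactant protein C, was the top gene in every library (named after its values were seen) and took 6.13% to 7.37% of the reads. On the first principal component, which held 56.6% of the variance, both wild-type libraries lay at negative values (-17.39 and -19.94) and both knockout libraries at positive ones (11.42 and 25.91). The second, which held 29.3%, crossed the genotypes. Wild type 1 (13.34) and knockout 2 (12.85) were positive there, and wild type 2 (-6.32) and knockout 1 (-19.87) negative. Correlations of log2(FPKM + 1) across genes lay between 0.9736 and 0.9899, and no pair of libraries agreed within sampling noise. Xist was at 184 to 212 FPKM in all 4 libraries, and Ddx3y, Kdm5d and Eif2s3y, which lie on the Y chromosome, were listed at 0.

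Nfe2l2 itself (chromosome 2, 75675513 to 75704641, minus strand, mm10) fell from 92.1 ± 5.95 FPKM (SD, n = 2) in wild-type tumours to 3.31 ± 0.496 FPKM (SD, n = 2) in knockout tumours. Its log2 fold change was -4.44 with a standard error of 0.13 (limma adjusted p = 0.000378). The knockout libraries held 129 and 98 reads of the gene, against 4092 and 3659 in the wild-type libraries. A deletion of some exons can leave reads from the rest of a gene, and where in the gene these reads lay is not analysed here.

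Of 13147 genes tested, 15 changed, 10 upwards and 5 downwards. Besides Nfe2l2, the genes that fell were mostly glutathione enzymes. Gsta3, a glutathione S-transferase (chromosome 1, 21240589 to 21265661), went from 21.3 ± 1.00 to 2.86 ± 0.732 FPKM (SD, n = 2 each). Gpx2, a glutathione peroxidase (chromosome 12, 76792333 to 76795554), went from 9.60 ± 0.417 to 1.37 ± 0.130 FPKM. Gstm1, another glutathione S-transferase (chromosome 3, 108012255 to 108017973), went from 224 ± 33.2 to 57.2 ± 6.89 FPKM. Limma's adjusted p was 0.0108 for Gsta3 and Gpx2 and 0.024 for Gstm1, and their log2 fold changes were -2.54 ± 0.16, -2.16 ± 0.13 and -1.95 ± 0.15 (SE). The remaining gene that fell was Igkv9-120, an immunoglobulin kappa variable segment (chromosome 6, 68049983 to 68050456), from 7.19 and 6.27 FPKM in wild type 1 and 2 to 1.42 and 1.01 FPKM in knockout 1 and 2 (limma adjusted p = 0.0302). Gsta3, Gstm1 and the kappa segments belong to families of similar genes, and their values depend on how shared reads were counted.

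Genes that rose included several of neutrophils and inflammation. S100a9 and S100a8, which encode the subunits of calprotectin, lie on chromosome 3 (90692632 to 90695721 and 90668978 to 90670035). S100a9 went from 7.78 and 11.3 FPKM in wild type 1 and 2 to 43.6 and 40.3 FPKM in knockout 1 and 2, and S100a8 from 8.33 ± 0.0476 to 29.5 ± 0.0499 FPKM (SD, n = 2 each). Csf3r, the receptor for granulocyte colony-stimulating factor (chromosome 4, 126024550 to 126044440), went from 4.62 ± 0.173 to 13.9 ± 0.220 FPKM. Il1b, which encodes interleukin-1 beta (chromosome 2, 129364570 to 129371139), went from 8.37 ± 0.0396 to 20.3 ± 1.57 FPKM. Ltb, which encodes lymphotoxin beta (chromosome 17, 35194439 to 35196320), was 2.62 times as high in knockout tumours, and the interferon-inducible Ifi27l2a (chromosome 12, 103442167 to 103443680) 2.70 times. Limma's adjusted p for these genes lay between 0.0108 for S100a8 and 0.0455 for Ltb and Ifi27l2a, and their log2 fold changes between 1.18 for Il1b and 2.04 for S100a9.

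The other genes that rose were Igfbp6, Col6a1, Prm1 and Igkj1. Igfbp6, an insulin-like growth factor binding protein (chromosome 15, 102144362 to 102149511), went from 4.11 ± 0.0596 to 13.0 ± 0.390 FPKM, and Col6a1, a collagen VI chain (chromosome 10, 76708792 to 76726168), from 26.5 ± 0.811 to 63.3 ± 2.84 FPKM (SD, n = 2 each; limma adjusted p = 0.0255 for both). Prm1, which encodes the sperm nuclear protein protamine 1 (chromosome 16, 10796326 to 10805839), had 4 and 0 reads in the wild-type libraries and 74 and 67 in the knockout libraries, a ratio of 43.3 after scaling to library totals (95% exact counting interval 16.6 to 161.2; limma adjusted p = 0.0108). Igkj1, a kappa joining segment of very short length (chromosome 6, 70722562 to 70722599), had 0 and 0 reads against 3 and 2, so that its call (limma adjusted p = 0.0261) rests on 5 reads and no fold is given.

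**Figure D1:**
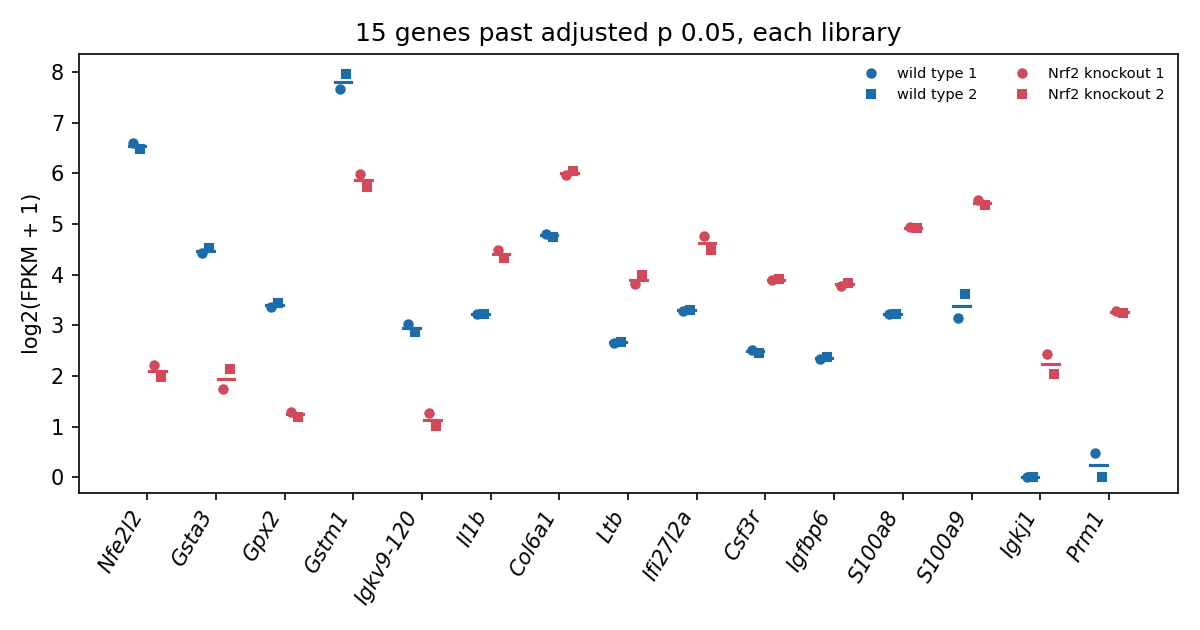
Expression of the 15 called genes in each library, as log2(FPKM + 1) on the vertical axis; circles and squares are libraries 1 and 2, blue wild type and red Nrf2 knockout, and lines are group means (n = 2). In every gene both knockout libraries lie on the same side of both wild-type libraries, with Nfe2l2 at 96.3 and 87.9 FPKM against 3.66 and 2.96.

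The number of calls depended on single libraries and on the filter. It was 252 without knockout 1, 55 without knockout 2, 10 (5 higher) without wild type 1 and 11 (6 higher) without wild type 2, and 1 gene, Nfe2l2, was called with no filter on low values. With quantile normalization 6 genes were higher and 5 lower. Of the 15 genes, 6 (Nfe2l2, S100a8, S100a9, Gsta3, Gpx2 and Gstm1) were called with each library left out in turn. At an unadjusted p under 0.05 limma gave 2020 genes, 1099 higher and 921 lower, where 657 would be expected by chance. The groups did not overlap for 48.1% of the tested genes, where chance gives 33.3%.

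The list of NRF2 target genes was lower in knockout tumours (camera in limma, adjusted p = 1.1e-06). With an estimated correlation its adjusted p = 0.349, and with fry 0.0943. Of 46 tested members 3 were called, all downwards (Gsta3, Gpx2 and Gstm1), and 11 were lower when adjusted over the list alone. The list median was a log2 fold change of -0.18. The aldehyde oxidase Aox1 stood at 27.8 ± 0.382 FPKM in wild-type and 10.8 ± 2.24 FPKM in knockout tumours (SD, n = 2 each; limma adjusted p = 0.0696). Some well-known members, chosen after their values were seen, were not called over all genes. Among the 11 lower when adjusted over the list alone were Txnrd1, a thioredoxin reductase, with a log2 fold change of -0.73 ± 0.11 (SE), and Srxn1, sulfiredoxin, at -0.63 ± 0.13. The cystine transporter Slc7a11, also among them, was at 1.86 ± 0.202 FPKM in wild-type and 0.745 ± 0.0262 in knockout tumours (SD, n = 2 each). Outside the 11, Hmox1, heme oxygenase 1, was at -0.10 ± 0.12, and Gclc and Gclm, the subunits of glutamate-cysteine ligase, at -0.17 ± 0.11 and -0.10 ± 0.14; Gclm was at 0.08 without knockout 1. Regulators of the pathway gave no call as a list (9 members, median -0.03, camera adjusted p = 0.684), and Keap1, the adaptor that targets NRF2 for degradation, was at -0.25 ± 0.11.

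Lists of immune cells were higher in knockout tumours. For T cell markers the median log2 fold change over 17 members was 0.86 (camera in limma, adjusted p = 1.06e-12; adjusted p = 0.303 with an estimated correlation). Of these, 16 lay higher in both knockout libraries than in both wild-type libraries, as did 22.7% of all tested genes; 0 were called over all genes and 14 when adjusted over the list alone, with limma unadjusted p under 0.05 for 14. Trbc2, a T cell receptor constant segment, went from 3.00 ± 0.360 to 7.81 ± 0.435 FPKM (SD, n = 2 each), and Il7r, the interleukin 7 receptor, from 1.24 ± 0.0232 to 3.23 ± 0.395 FPKM. Neutrophil markers had a median of 1.09 over 12 members (adjusted p = 4.09e-08; adjusted p = 0.303 with an estimated correlation), 3 of them called, and 8 when adjusted over the list alone. B cell and plasma cell markers had a median of 0.69 over 14 members (0.37 without knockout 2; adjusted p = 1.1e-06; adjusted p = 0.303 with an estimated correlation), with 8 higher when adjusted over the list alone, among them Cd79a at 1.62 ± 0.0913 and 4.19 ± 1.21 FPKM. Cytotoxic lymphocyte markers had a median of 0.74 over 5 members (adjusted p = 7.18e-05; adjusted p = 0.318 with an estimated correlation), 4 of them higher when adjusted over the list alone. Fry in limma called these lists, with adjusted p = 0.0394, 0.0168, 0.0394 and 0.0446 for T cell, neutrophil, B cell and cytotoxic markers.

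Mediators of inflammation were higher as lists too. Chemokines had a median log2 fold change of 0.88 over 19 members (camera in limma, adjusted p = 2.51e-08; adjusted p = 0.303 with an estimated correlation), with 0 members called over all genes, 12 higher when adjusted over the list alone and limma unadjusted p under 0.05 for 13 higher and 1 lower. Ccl17 and Ccl22, ligands of the receptor CCR4, stood at 36.3 ± 19.5 and 17.1 ± 6.10 FPKM in knockout tumours against 6.17 ± 2.10 and 3.90 ± 1.15 in wild type (SD, n = 2 each), and the neutrophil attractant Cxcl1 at 25.7 ± 0.789 against 12.2 ± 1.39. NF-kB target genes had a median of 0.40 over 15 members (adjusted p = 1.35e-07; adjusted p = 0.349 with an estimated correlation), 10 of them higher when adjusted over the list alone. Inflammatory cytokines and growth factors had a median of 0.32 over 17 members (adjusted p = 3.1e-05; adjusted p = 0.312 with an estimated correlation), with Il1b called and 4 higher when adjusted over the list alone. Genes of MHC class I presentation had a median of 0.33 over 17 members (adjusted p = 1.1e-06; adjusted p = 0.318 with an estimated correlation), 8 of them higher when adjusted over the list alone; B2m, the shared light chain, was at 519 ± 31.6 FPKM against 341 ± 31.5. Interferon-stimulated genes had a median of 0.32 over 26 members (0.20 without wild type 2; adjusted p = 3.18e-05; adjusted p = 0.447 with an estimated correlation), with 0 higher when adjusted over the list alone and limma unadjusted p under 0.05 for 7. The interferon call was lost with the filter at an FPKM of 10. Fry in limma gave adjusted p = 0.0394 for chemokines and for the cytokine list, and did not call the NF-kB, MHC class I and interferon lists (0.089, 0.0822 and 0.272).

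Macrophage lists were higher by camera at the preset correlation, except for that of alveolar macrophages. Of the 20 pan-macrophage markers, 0 were higher when adjusted over the list alone, and 4 had a limma unadjusted p under 0.05, all higher. Adgre1 and Csf1r, members chosen after their values were seen, were at log2 fold changes of -0.03 and 0.07. Alternatively activated macrophage genes had a median of 0.58 over 14 members (0.96 without knockout 1 and 0.26 without knockout 2; camera in limma, adjusted p = 0.000725; adjusted p = 0.349 with an estimated correlation), 6 of them higher when adjusted over the list alone. The elastase Mmp12 was at 48.2 ± 18.6 FPKM in knockout and 13.5 ± 0.519 in wild-type tumours (SD, n = 2 each). Of the 14, 8 lay higher in both knockout libraries than in both wild-type libraries and 2 lower, against 22.7% and 25.4% of all tested genes. Among the 2 was Spp1, chosen after its values were seen, at 211 ± 24.6 FPKM in knockout and 303 ± 76.7 in wild-type tumours. Classically activated macrophage genes had a median of 0.18 over 7 members (0.30 without wild type 1; adjusted p = 0.00248; adjusted p = 0.34 with an estimated correlation; fry adjusted p = 0.0394), and pan-macrophage markers of 0.26 over 20 (0.16 without knockout 2; adjusted p = 0.000988; adjusted p = 0.447 with an estimated correlation). Dendritic cell markers had a median of 0.41 over 10 members (adjusted p = 2.22e-05; adjusted p = 0.349 with an estimated correlation). Alveolar macrophage markers were not called as a list (18 members, median 0.02, mean -0.03, camera adjusted p = 0.924), and 3 were higher and 3 lower when adjusted over the list alone. Among them the scavenger receptor Marco was at 20.9 and 15.4 FPKM in the wild-type libraries and at 3.78 and 1.34 in the knockout libraries, and the protease Ctsk at 37.5 and 39.6 against 78.5 and 68.7 (limma adjusted p = 0.0852 and 0.0722). Regulatory T cell and exhaustion genes had a median of 0.23 over 11 members (adjusted p = 0.0452; adjusted p = 0.447 with an estimated correlation), which was 0.36 without wild type 1. It was not called without knockout 1 (-0.07, adjusted p = 0.166), knockout 2 (0.11, adjusted p = 0.121) or wild type 2 (0.18, adjusted p = 0.264), nor with quantile normalization or a pseudocount of 10. Fry did not call the alternatively activated, pan-macrophage, dendritic and regulatory T cell lists (adjusted p = 0.153, 0.294, 0.171 and 0.227). Without wild type 2 the pan-macrophage list was not called either (adjusted p = 0.106). MHC class II genes (median 0.14 over 12 members, camera adjusted p = 0.0561) and T helper cytokines and receptors (median 0.00 over 5 members, camera adjusted p = 0.787) were not called.

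Markers of red blood cells were higher in the same libraries as these immune lists. Erythroid markers had a median log2 fold change of 1.40 over 6 members (camera in limma, adjusted p = 3.42e-06; adjusted p = 0.349 with an estimated correlation). The 4 haemoglobin genes tested summed to 244 and 486 FPKM in wild type 1 and 2 and to 1186 and 1084 FPKM in knockout 1 and 2. Mitochondrially encoded genes took 1.39% and 1.72% of the reads in the wild-type libraries and 2.95% and 2.26% in the knockout libraries.

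Stromal and airway lists were also higher, with wild type 2 lowest and knockout 2 highest. Fibroblast and matrix genes had a median of 0.56 over 20 members (camera in limma, adjusted p = 2.46e-06; adjusted p = 0.486 with an estimated correlation), with Col6a1 called and 6 higher when adjusted over the list alone. Endothelial markers had a median of 0.52 over 18 members (adjusted p = 0.000139; adjusted p = 0.538 with an estimated correlation), and smooth muscle and pericyte markers of 0.46 over 10 (adjusted p = 0.000725; adjusted p = 0.468 with an estimated correlation). Ciliated cell markers had a median of 0.46 over 9 members (adjusted p = 0.00898; adjusted p = 0.545 with an estimated correlation), club cell markers of 0.32 over 13 (adjusted p = 0.0468; adjusted p = 0.486 with an estimated correlation), and complement and acute phase genes of 0.66 over 9 (adjusted p = 0.0322; adjusted p = 0.556 with an estimated correlation). Relative to the mean of the 4 libraries, the endothelial list had a median of 0.07 and -0.63 in wild type 1 and 2 and of -0.03 and 0.48 in knockout 1 and 2. The fibroblast list had -0.00 and -0.51 against 0.01 and 0.52. Without wild type 2, 8 of the 27 called lists were no longer called. Among them, endothelial, ciliated, club and complement medians were then 0.22, 0.21, 0.17 and 0.41, and that of smooth muscle 0.38 (camera adjusted p = 0.147, 0.147, 0.31, 0.286 and 0.0581), while the fibroblast list was at 0.26 and called. Without knockout 2 the endothelial, smooth muscle and fibroblast lists were at 0.20, 0.15 and 0.33 and called, and the ciliated and complement lists, at 0.30 and 0.20, were not (0.0965 and 0.29). Without wild type 1 the endothelial, ciliated and club lists were at 0.82, 0.71 and 0.59, and the club list was at 0.48 without knockout 1 and 0.60 without knockout 2. The club call was also lost with quantile normalization, without the trend, with no filter, with a pseudocount of 10 and with limma-voom, the ciliated call with no filter, and the complement call with no filter and with the filter at an FPKM of 10.

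Markers of alveolar epithelium and of cell division were not called as lists. Alveolar type 2 markers had a median of -0.04 over 19 members (mean 0.25, camera adjusted p = 0.924), alveolar type 1 markers of 0.10 over 14 (camera adjusted p = 0.271) and proliferation genes of 0.01 over 25 (mean -0.03, camera adjusted p = 0.617). For alveolar type 2 markers, camera's direction was downwards and the mean was positive. The member Chia1 was at 282 FPKM in knockout 2 and 1.45 to 8.72 in the other libraries. Dedifferentiation and gastric-like genes (median -0.15 over 14 members), xenobiotic cytochrome P450s (median 0.31 over 11), hypoxia genes (median 0.19 over 13) and cardiac muscle markers (median 0.21 over 5) gave camera adjusted p = 0.111, 0.924, 0.109 and 0.761.

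Genes transcribed in response to MAPK signalling were lower as a list, with a median log2 fold change of -0.28 over 19 members (camera in limma, adjusted p = 3.18e-05; adjusted p = 0.34 with an estimated correlation). Over all genes 0 were called, 1 was lower when adjusted over the list alone, and limma's unadjusted p was under 0.05 for 8, all lower. The MAPK list was not called by fry (adjusted p = 0.243). The receptor tyrosine kinase Epha2 stood at 261 ± 8.15 FPKM in wild-type and 165 ± 11.9 in knockout tumours, and cyclin D1 (Ccnd1) at 208 ± 9.16 and 161 ± 22.9 (SD, n = 2 each). Pentose phosphate and glycolysis genes had a median of -0.12 over 21 members (adjusted p = 0.0238; adjusted p = 0.486 with an estimated correlation), a call lost without wild type 2 or knockout 1 (-0.06, adjusted p = 0.31; -0.11, adjusted p = 0.0992); it was -0.20 without wild type 1 and -0.18 without knockout 2. Among its members was G6pdx, which feeds the pentose phosphate pathway, at 35.6 ± 0.114 FPKM in knockout and 48.7 ± 2.70 in wild-type tumours. Lipid and cholesterol synthesis genes had a median of -0.17 over 19 members (camera adjusted p = 0.0248, and 0.465 with an estimated correlation). That call was lost without wild type 1 (median -0.1496), without knockout 2 (median -0.1476) and with quantile normalization. The pentose phosphate and lipid calls were both lost with the filters at an FPKM of 5 and 10. Targets of p53 had a median of 0.25 over 14 members (adjusted p = 0.00234; adjusted p = 0.349 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 129 ± 28.1 FPKM against 74.7 ± 3.39. Immediate early and heat shock genes had a median of 0.16 over 20 members (adjusted p = 0.0262; adjusted p = 0.441 with an estimated correlation), a call lost without wild type 1 or knockout 1 (0.10, adjusted p = 0.154; 0.17, adjusted p = 0.119).

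**Figure D2:**
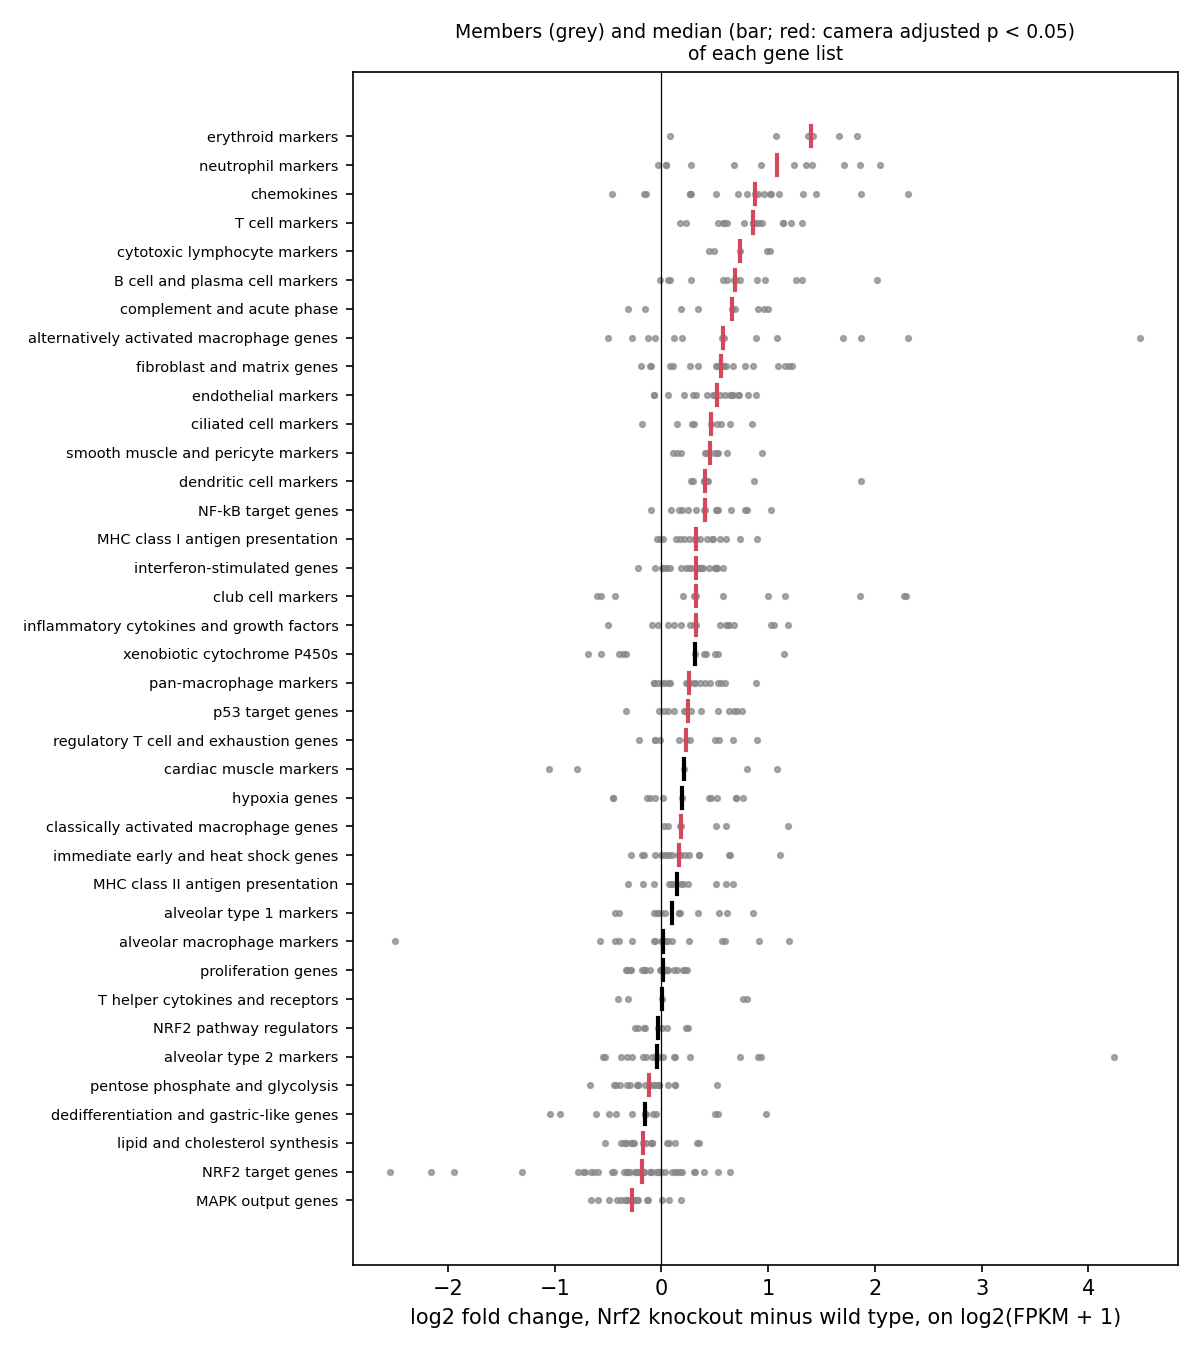
Log2 fold change, knockout minus wild type on log2(FPKM + 1), of every tested member (grey points) of the 38 lists tested, with the list median as a bar that is red at a camera adjusted p under 0.05. Erythroid (1.40), neutrophil (1.09) and chemokine (0.88) lists have the highest medians and the MAPK list (-0.28) the lowest.

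Of the 38 lists tested, camera with the preset correlation called 23 higher and 4 lower. With an estimated correlation 0 were called, and 5 had a limma unadjusted p under 0.05. That setting has 2 residual degrees of freedom, so its lack of calls does not tell correlated members from low power. Fry called 7 higher and 0 lower. Among the lists that fry did not call were the erythroid, fibroblast, endothelial and p53 lists (fry adjusted p = 0.153, 0.405, 0.488 and 0.262). Some genes belong to more than 1 list, so the list calls are not separate findings. Il1b is in the cytokine and classically activated lists, and Ccl17 and Ccl22 are in the chemokine and alternatively activated lists. G6pdx is in the NRF2 target and pentose phosphate lists. Lists of fewer than 5 tested members were not tested. Mesothelial markers (4 members, median 1.02), lymphatic endothelial markers (4, median 0.01), mast cell, basophil and eosinophil markers (2, median 0.38), neuroendocrine markers (2, median 0.40) and adipocyte markers (1, 1.19) had 0 members called, and limma's unadjusted p was under 0.05 for 3, 1, 1, 1 and 1 of them.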

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

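The limma-voom fit and the filters at an FPKM of 10 and on 10 recovered reads were chosen after seeing the data; the alternatives planned for count tables were not run because the values are FPKM. Nfe2l2 was called in all 14 settings that refitted the genes, with log2 fold changes from -4.80 to -2.94. Of the 27 lists called, 16 were called by camera at the preset correlation in every refit with 5 or more tested members. The neutrophil, chemokine, NF-kB, NRF2 target and MAPK lists were called in all 14. The T cell, dendritic cell and classically activated lists could be tested in 12, and the cytotoxic list in 10. The filters at an FPKM of 5 and 10 left these lists too few members, so their calls were not tested at those filters. The other 11 of the 27 lists each lost the call in at least 1 refit. Il1b, Ltb and Ifi27l2a were called in 7 of the 14 settings, and lost with quantile normalization, without the trend, with no filter, with a pseudocount of 10, with limma-voom and without either wild-type library. Leaving out 1 library, where the lone library is assumed to vary like the others, gave 10 to 252 genes changed, 5 to 184 higher and 5 to 68 lower. Of the 15 genes, 13 were shared with the 252 found without knockout 1, and 7 were called without either wild-type library. The cause of these shifts was not tested.

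Quantile normalization, limma without the trend and a pseudocount of 10 each gave 6 genes higher. With no filter 1 gene was called, 0 higher and 1 lower. The stricter filter gave 8 genes lower and 2 lists lower, and the filter at an FPKM of 10, which tests fewer genes, gave 27 genes, 17 higher and 10 lower, with 14 lists higher. Limma-voom called 8 genes, 4 of them higher, 7 of them shared with the 15. S100a8 lost its call with limma-voom, S100a9 without the trend, and Prm1 with limma-voom and with a pseudocount of 0.1. At an adjusted p under 0.1, 65 genes passed, 46 higher and 19 lower. With an estimated correlation 0 lists were higher and 0 lower; fry gave 7 higher and 0 lower. With the replicate number as a block, 69 genes were called, 54 higher and 15 lower, all 15 genes included. The labels do not say that a number pairs mice, and deviations of the first library of each genotype correlated at -0.306 across genes, so the numbers were taken as names only. The cause was not tested for these settings.

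Values that were not called changed sign in places. With quantile normalization Ddc was at -0.0717, Flt4 at -0.0413 and the proliferation list at -0.066. The P450 list was at -0.009 with the stricter filter, Lyve1 at 0.0017 with a pseudocount of 0.1, and Flt4 at -8e-04 and the T helper list at -0.0013 with a pseudocount of 10. Without 1 library, ranges were -0.10 to 0.17 for Ddc, -0.43 to 0.41 for Lyve1, -0.24 to 0.72 for Kit, -0.40 to 0.46 for Flt4, -0.20 to 0.062 for Pdpn, -0.27 to 0.077 for Gclm and -0.17 to 0.0366 for Xist. For list medians they were -0.22 to 0.50 (T helper), -0.14 to 0.0873 (alveolar macrophage), -0.0453 to 0.34 (alveolar type 1), -0.0704 to 0.0207 (proliferation), -0.0781 to 0.39 (P450), -0.0166 (cardiac muscle, tested without wild type 2) and -0.0661 to 0.36 (regulatory T cell and exhaustion, which was called). The cause was not tested. Depth limits genes with few reads, such as Igkj1 with 5.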

Other observations

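Tests of the explanations below were chosen after the result was seen for the name-based removal, both accounts of Prm1, blood and the share of tumour cells. Those for ribosome biogenesis, level and length, and chromosome 2 were chosen before their own results were seen. The pattern in knockout 1 that the ribosome biogenesis test addresses had by then been found in these data. Knockout 2 held a group of genes that lay well above every other library, chosen after their values were seen. There, 68 genes lay more than 1 on the log2 scale above all other libraries, against 5, 6 and 8 such genes in wild type 1, wild type 2 and knockout 1. Retnla, a secreted protein induced in alternatively activated macrophages and airway epithelium, was at 4276 FPKM in knockout 2 and at 36.0, 13.6 and 62.0 FPKM in wild type 1, wild type 2 and knockout 1. The anion exchanger Slc26a4 was at 274 FPKM against 1.06 to 5.45, the acidic chitinase Chia1 at 282 against 1.45 to 8.72, and the peptide hormone Apln at 263 against 9.41 to 14.0. Il33, an epithelial cytokine, was at 171 FPKM against 60.4 to 66.1, and C3, the central complement component, at 685 against 208 to 280. Some of the 68 were also higher in knockout 1 than in wild type. Ccl17 was at 50.1 FPKM in knockout 2 and 22.6 in knockout 1, against 7.65 and 4.685 in wild type 1 and 2.

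In knockout 1, 18 genes lay more than 1 on the log2 scale below every other library, and many of them share a name. Among these, named here after their values were seen, Gm42418 was at 13.7 FPKM against 695 to 1797, Hsp90aa1 at 4.60 against 167 to 197, and Rrp1 at 5.43 against 84.4 to 86.4. All 8 tested genes named Rrp and a number were among them, with a median of -2.01 (95% bootstrap interval -2.77 to -1.71). This name was picked after these genes were seen to be low, so the median and interval describe the pattern and are no separate test. Ribosome biogenesis genes not named Rrp had a median of -0.15 (-0.21 to -0.10) over 38 genes, measured against the mean of the other libraries. They were thus slightly lower in knockout 1. These values argue against a fall in ribosome biogenesis as large as that of the Rrp genes, and do not exclude a small one. A candidate explanation is that reads of that library were removed against a set of sequences collected by a ribosomal RNA keyword; the other 10 genes have other symbols, and no biological explanation was tested beyond ribosome biogenesis.

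Prm1 had 141 reads in the knockout libraries and 4 in the wild-type libraries, a ratio of 43.3 after scaling to library totals. Prm2, Tnp1 and Tnp2, abundant in the same spermatids, had 1 read in all in the knockout libraries (upper Poisson limit 5.57), which argues against male germ cell RNA in the knockout samples. Prm1 sequence carried by the targeted allele may account for it. That cannot be told apart from another source of Prm1 transcripts in knockout tissue, because the positions of the reads within Prm1 are not analysed here and the difference coincides with genotype.

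T cell and neutrophil markers together (29 genes) had a median log2 fold change of 0.87. Among 10000 random lists matched on level and length the highest median was 0.372 (a share of 0.01% when the list itself is counted), which argues against a trend with either. Alveolar macrophage and alveolar type 1 markers (32 genes) were lower by 0.84 (95% bootstrap interval 0.58 to 1.11). This difference was 0.73 to 0.94 with 1 library left out, and 0.85 (0.58 to 1.13) for alveolar macrophage markers alone. The intervals resample genes, not samples. These lists did not rise alike, but alveolar macrophage markers split, with 3 higher and 3 lower when adjusted over the list alone. Expression of the markers by tumour cells was not tested, so the comparison does not decide whether a lower share of tumour cells was the whole cause. Other lists were nearer, below by 0.31 (0.03 to 0.63) for fibroblast, 0.35 (0.05 to 0.63) for endothelial, 0.41 (0.13 to 0.77) for ciliated, 0.41 (0.15 to 0.73) for smooth muscle, 0.55 (-0.39 to 0.83) for club and 0.61 (0.33 to 0.88) for pan-macrophage markers, so a lower share may contribute. More blood in the knockout samples may contribute: wild type 2 exceeded wild type 1 by 0.97 in the haemoglobin genes and by -0.008 (-0.149 to 0.074) in these markers, but a single pair of libraries decides nothing, and recruitment of immune cells was not tested.

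A further hypothesis was that sequence of another strain around the targeted locus changes its neighbours. Of 93 tested genes within 10 Mb of Nfe2l2, 22.6% had an unadjusted p under 0.05 in limma, against 15.3% of the other genes. The odds ratio was 1.61 (Fisher's exact test, two-sided p = 0.06), so that a carried-over segment may exist but was not shown, and neighbouring genes are not independent.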
